A study of Mus musculus with 52 samples.

How the data were processed

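The samples were 384-well plates of single CD45-positive cells, the pan-leukocyte gate, sorted from mouse MCA tumours of wild type C57/Bl6 mice and of mice without Trem2 at day 10 and day 19 after tumour cell inoculation. Per the labels, dead cells and doublets were excluded by gating before sorting and libraries were made with the MARS-seq 2.0 protocol, which tags the 3' ends of polyadenylated RNA with a cell barcode and a molecular identifier (UMI). The authors deposited, for each plate, a table of whole-number UMI counts per gene and well, not normalized. Base calling used bcl2fastq 2.15.0.4 and the genome build was mm10, per the submitters' processing notes. The aligner, the gene annotation and the filter on molecules were not given in the sources used here. A design text in the series record speaks of another assay and was not used.

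Each plate is 1 sample, placed in its group by the strain and time point in the labels, which gave 7 wild type and 12 knockout plates at day 10, and 21 wild type and 12 knockout plates at day 19. The labels do not tie plates to animals or tumours, so p-values measure only the spread between plates, which may be technical. Plate numbers fall into 4 series (79, 81, 82 and 83), each of which was 1 sequencing batch in the well table. All day 10 plates were of series 79, series 81 held 9 wild type plates of day 19, and series 82 and 83 each held 6 plates of either genotype. Total UMIs of kept cells per plate were 1047355 to 1396074 in wild type and 630211 to 1392157 in knockout plates at day 10, and 285362 to 1192497 and 740491 to 1106711 at day 19. No plate was a copy of another: the lowest chi-square per degree of freedom between plates of a group was 3.23 over the 2000 most abundant genes.

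The choices in this paragraph and the tests, lists and naming rule below were made before the data were examined. Wells listed with 1 cell were kept with at least 400 UMIs over named genes and a mitochondrial share of at most 30%, spike-ins left out. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes without Trem2, sex-linked, mitochondrial, ribosomal protein, immunoglobulin, haemoglobin and histone genes gave 30 principal components, 15 nearest neighbours and Leiden clusters at resolution 1 (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15). Clusters were named from fixed marker lists by the class whose detected markers were highest, and the name is written with "-like" or as a class because it was rebuilt here. Monocyte-like and macrophage-like clusters formed 1 monocyte-macrophage class, which was clustered again at resolution 0.6. No doublet caller was run, since 1 cell was sorted per well after a doublet gate.

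Cells were not treated as replicates. Counts were summed per plate and class where a plate held at least 20 cells of the class, and tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust quasi-likelihood fit and F-test, Benjamini-Hochberg adjustment at 0.05). All groups entered 1 fit with plate series as a covariate, so the day 19 genotype contrast rests on series 82 and 83. The contrasts between days had no series term, since day and series cannot be told apart. Log2 fold changes carry their standard error (SE), and levels are in CPM, counts divided by the library size of the plate, with the SD over plates. CPM of genes given with a fold change are TMM-scaled, and those of Trem2, Wdfy1 and G530011O06Rik given per cell set are plain. Numbers of plates in a direction count knockout plates on that side of the wild type mean of their series. Class shares are percentages of the kept cells of a plate and were compared by 2-sided exact permutation of plates, at day 19 within series 82 and 83, with Benjamini-Hochberg adjustment over the 9 classes.

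Gene lists were fixed beforehand: the Trem gene cluster and neighbours, Trem2-dependent lipid and phagocytosis genes known from microglia, regulatory macrophage genes recalled from the study itself, interferon response, MHC class II, MHC class I and immunoproteasome, complement and resident macrophage, monocyte, hypoxia and glycolysis, inflammatory cytokines and NF-kB targets, proliferation, cytotoxic effector, T cell exhaustion and checkpoint, regulatory T cell, naive and memory T cell, dissociation stress, and stroma and tumour cell transcripts. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry (limma 3.58.1), adjusted over the lists of a class and contrast. A list of erythrocyte transcripts had fewer than 3 measured members in every class and was not tested. Named genes are Trem2, the 10 risen and 10 fallen genes with the smallest p among those past the threshold with an absolute log2 fold change of at least 0.5 (5 and 5 for the lymphocyte, interaction and day contrasts), up to 4 members of each list with the smallest p, and members of the Trem cluster past the threshold. Some genes that met this rule are not reported. Ribosomal, mitochondrial and sex-linked genes are given as groups. Coordinates are those of GENCODE M21 on mm10, where 10007 of the 10183 genes tested over all cells had a gene of the same name.

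Before use, the tests were checked on counts simulated from the real means, library sizes and dispersions with 200 genes changed by known folds. In the monocyte-macrophage class the day 10 contrast called 33.8% of genes changed 1.5-fold, 81.8% of those changed 2-fold and 98.5% of those changed 4-fold among 8433 genes, and the day 19 contrast 39.4%, 83.3% and 100% among 8412 genes. For T cells these were 19.7%, 63.3% and 95.4% at day 10 among 1888 genes and 16.1%, 45.8% and 87.1% at day 19 among 1919 genes, and for NK cells at day 10 1.89%, 19.7% and 72.6% among 2805 genes. Between 1 and 8 unchanged genes were called per simulation. The share test passed an unchanged class in 9 of 200 simulations at day 10 and in 7 of 200 at day 19, and a class raised by 3 points in 193 and 200 of 200. These simulated plates were independent and varied only by the sampling of cells, and p was not adjusted. Real plates could spread more, as NK cell-like shares at day 10 did (SD 2.39 points in knockout and 3.45 in wild type). For such classes the power given is too high.

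Alternatives planned beforehand were DESeq2 1.42.0 as the test and for size factors, no filter on low counts, no series term, each series alone, other minimums of UMIs, cells and mitochondrial share, other clustering resolutions, classes from marker sums, macrophage-named clusters alone, cells thinned to 400 UMIs, and pooled cells or plates. Added after the data were seen were fits without plates that kept under 60% of their wells, with neighbouring plates summed in pairs, with a term for Y-linked transcripts, without the 4 knockout plates of day 19 that held such transcripts, without series 81, with series 82 alone in blocks of 4 plates by number, without the T cell-like plate with the most Klra5, without each NK cell-like plate in turn, with mitochondrial rRNA left out of the mitochondrial share, with a minimum of 5 cells, and a clustering without the genes called. Every value column of the deposited tables that belonged to a sample was used. NK cells at day 19 could not be tested as planned, because no wild type plate of series 82 or 83 held 20 such cells.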

Results

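Trem2, which encodes a lipid-sensing surface receptor of macrophages, was nearly absent from the tumour monocytes and macrophages of knockout mice on both days. In monocyte-macrophage-like cells Trem2 (chromosome 17, 48346401 to 48354147, mm10) averaged 196 ± 18.8 CPM (SD, n = 7 plates) in wild type and 8.82 ± 2.69 (n = 12) in knockout plates at day 10. At day 19 it averaged 226 ± 51.3 CPM over 21 wild type plates, 198 ± 31.9 over the 12 of them in series 82 and 83, and 10.5 ± 3.96 over 12 knockout plates. The log2 fold change was −4.46 ± 0.14 (SE; adjusted p = 1.42e-40) at day 10 and −4.33 ± 0.13 (adjusted p = 1.53e-42) at day 19, lower in 12 of 12 knockout plates each time. No knockout plate reached 20 CPM (highest 13.1 at day 10 and 19.7 at day 19), and no wild type plate fell under 130 (lowest 173 and 136). After filtering, 14260 cells remained (2146 wild type and 3198 knockout at day 10, 5213 and 3703 at day 19), with a median of 2570 UMIs and 1099 genes per cell. Monocyte-macrophage-like cells made up 1438, 2309, 3884 and 2953 of them in the same order.

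Transcripts of the X-linked Xist and of Y-linked genes, which tell female from male cells, differed between the genotypes at day 10. All 7 wild type plates of day 10 and all 21 of day 19 held more Xist than Y-linked counts, whereas all 12 knockout plates of day 10 held more Y-linked counts. At day 19, 4 knockout plates held mainly Y-linked counts and 8 mainly Xist. Genotype and sex of the cells were therefore fully confounded at day 10, and every day 10 difference below compares plates that also differed in these transcripts.

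**Figure D1:**
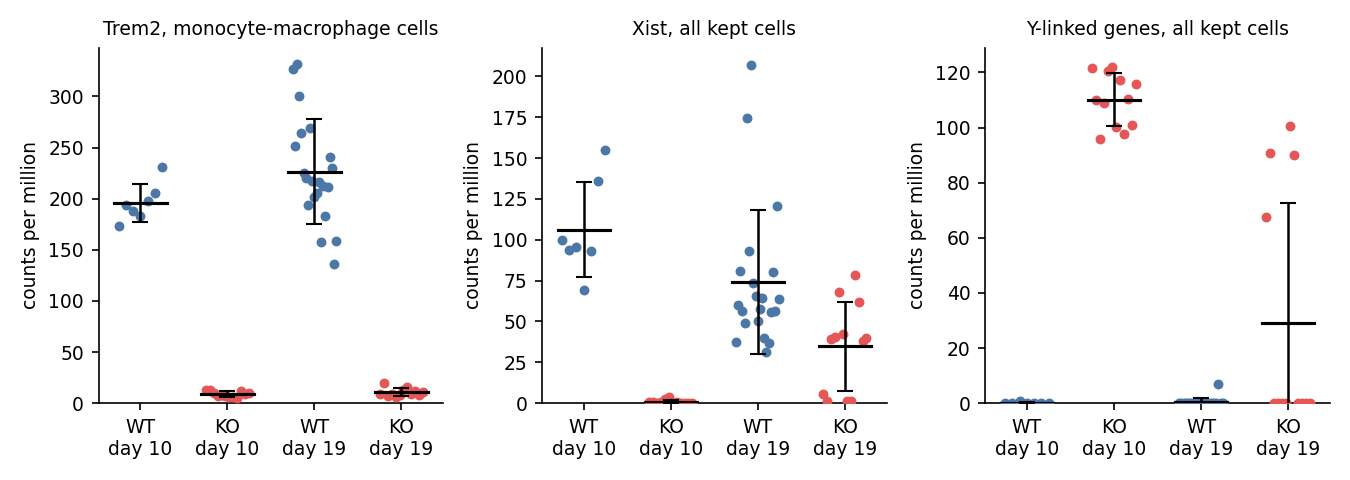
Trem2 in monocyte-macrophage-like cells (left), Xist (middle) and Y-linked transcripts (right) in all kept cells of each plate, in CPM, for the 4 groups. Points are plates and bars the mean ± SD; Trem2 averaged 196 and 8.82 CPM in wild type and knockout at day 10, and Y-linked transcripts marked all 12 knockout plates of day 10 and 4 of day 19.

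At day 10 knockout monocyte-macrophage-like cells carried less of the enzyme genes Nos2 (nitric oxide synthase) and Pla2g7 (platelet-activating factor hydrolase). They carried more of the resident-type macrophage genes Ms4a7, Mrc1 and Fcrls. Proliferation genes such as Birc5 were higher, and MHC class I genes and the GTPase genes Gbp2, Gbp4 and Iigp1 were lower. Pla2g7 fell from 855 to 431 CPM (log2 fold change −0.99 ± 0.10, adjusted p = 1.7e-11) and Nos2 from 118 to 24.5 CPM (−2.21 ± 0.23, adjusted p = 1.56e-09), each in 12 of 12 knockout plates. Ms4a7 rose from 498 to 754 CPM (0.60 ± 0.10, adjusted p = 2.51e-05) and Fcrls, an Fc receptor-like scavenger gene, from 17.5 to 114 CPM (2.61 ± 0.36, adjusted p = 2.2e-06), each in 12 of 12. Of 8671 genes tested, 250 rose and 268 fell, and 351 of these changed by at least 0.5 on the log2 scale. With a term for Y-linked transcripts 134 genes were called (63 risen and 71 fallen), and 26 genes followed for this contrast lost their call. They are among 64 values followed, some of which did not pass as planned. The knockout plates of day 19 alone set this term, so it cannot show what sex did at day 10. With neighbouring plates summed in pairs 246 were called, and 12 of the genes followed lost their call. Knockout cells of the class also lay more often in the cluster led by Ch25h, Ccl12 and Fcrls (11.99 ± 4.45% and 3.36 ± 1.70%, exact permutation adjusted p = 0.00327). Genes called here are among its leading genes. Clustered without the called genes, the cluster led by Ch25h, Ccl7 and Olfml3 did not pass (16.9 ± 4.62% and 12.4 ± 3.31%, exact permutation adjusted p = 0.0811). In that clustering 5 of 12 clusters still passed. A difference over the class therefore does not separate another mix of cells from other levels within cells.

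Among the other risen genes, Cd63, a lysosomal tetraspanin gene, rose (68.1 to 142 CPM, 1.07 ± 0.16, adjusted p = 2.2e-06, 12 of 12). Its annotated pseudogene Cd63-ps moved with it (1.07 ± 0.18, adjusted p = 4.81e-05, 12 of 12). The 2 may share reads, which was not tested. Timp2, a metalloproteinase inhibitor gene (1.01 ± 0.16, adjusted p = 6.12e-06), and the chromatin gene Hmgn1 (1.195 ± 0.18, adjusted p = 4.02e-06) rose in 11 of 12 plates. Ntpcr (0.94 ± 0.14, adjusted p = 2.2e-06), Prune2 (1.25 ± 0.22, adjusted p = 5.21e-05) and Rbbp7 (0.68 ± 0.12, adjusted p = 5.21e-05) rose in 12 of 12. The largest rise among the named genes was that of G530011O06Rik, a processed transcript near the end of the X chromosome (2.86 ± 0.30, adjusted p = 3.9e-11, 12 of 12). Besides Pla2g7 and Nos2, the named fallen genes were the ADP-ribosyl cyclase gene Bst1 (−0.99 ± 0.12, adjusted p = 1.55e-08), the Fc receptor gene Fcgr4 (−0.71 ± 0.09, adjusted p = 1.34e-07) and Rcbtb2 (−0.93 ± 0.13, adjusted p = 6.78e-07), all in 12 of 12. H2-Q7 (−0.74 ± 0.10), H2-Q6 (−1.04 ± 0.15), Ly6i (−1.42 ± 0.18), Gbp8 (−1.44 ± 0.21) and the microRNA locus Mir6953 (−0.92 ± 0.12) also fell in 12 of 12 (adjusted p = 2.39e-07, 1.07e-06, 5.35e-07, 6.78e-07 and 1.34e-07). Near-identical or overlapping genes leave the source of these reads uncertain. Of 175 ribosomal protein genes and pseudogenes 45 rose, and the calls included 13 X-linked and 2 Y-linked genes.

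The MHC class I list lay lower in knockout cells at day 10, as did the interferon and MHC class II lists, though these did not pass with an estimated correlation. Of 13 MHC class I and immunoproteasome genes 0 rose and 8 fell (10 adjusted over the list alone; median log2 fold change −0.31). Among them were H2-K1 (−0.44 ± 0.08, adjusted p = 6.06e-05), H2-D1 (−0.38 ± 0.07, adjusted p = 9.86e-05), the peptide transporter gene Tap1 (−0.46 ± 0.09, adjusted p = 0.00063) and Psmb9 (−0.45 ± 0.11, adjusted p = 0.00351), each in 12 of 12 plates. Camera gave this list an adjusted p of 8.23e-11, and 0.00313 with an estimated correlation. Of 26 interferon response genes 1 rose and 9 fell (1 and 13 adjusted over the list alone; median −0.21). These included Gbp4 (−1.23 ± 0.19, adjusted p = 1.02e-05), Gbp2 (−1.01 ± 0.17, adjusted p = 4.25e-05) and Iigp1 (−1.04 ± 0.17, adjusted p = 5.21e-05), each in 12 of 12. The list's adjusted p was 7.41e-07, but 0.122 with an estimated correlation. Of 9 MHC class II genes only the transactivator gene Ciita fell (−1.09 ± 0.25, adjusted p = 0.00351, 12 of 12), and 8 fell adjusted over the list alone (median −0.51). Cd74 (−0.51 ± 0.19, adjusted p = 0.119) and the protease gene Ctss (−0.18 ± 0.07, adjusted p = 0.0955) did not pass over all genes. This list had an adjusted p of 0.00025, and 0.122 with an estimated correlation.

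Inflammatory, monocyte and hypoxia lists lay lower as well, though none of them passed with an estimated correlation. Of 16 inflammatory cytokine and NF-kB genes 0 rose and 5 fell (9 adjusted over the list alone; median −0.57). These included the feedback inhibitor genes Tnfaip3 (−0.83 ± 0.18, adjusted p = 0.00241, 11 of 12), Nfkbia (−0.60 ± 0.14, adjusted p = 0.00351, 12 of 12) and Nfkbiz (−0.61 ± 0.15, adjusted p = 0.00838, 12 of 12). The list's adjusted p was 1.24e-07, but 0.0699 with an estimated correlation. Of 20 hypoxia and glycolysis genes 6 fell and 0 rose (9 fell adjusted over the list alone; median −0.30). Among them were the glycolytic genes Pkm (−0.39 ± 0.08, adjusted p = 0.000657, 12 of 12) and Hk2 (−0.64 ± 0.15, adjusted p = 0.00509, 11 of 12) and the hypoxia-inducible Ndrg1 (−0.87 ± 0.20, adjusted p = 0.00463, 11 of 12). The list's adjusted p was 5.89e-08, but 0.102 with an estimated correlation. Of 14 monocyte genes 4 fell and 0 rose (8 fell and 2 rose adjusted over the list alone; median −0.51). These included the coagulation factor gene F10 (−0.92 ± 0.20, adjusted p = 0.00259, 11 of 12), Gsr (−0.72 ± 0.16, adjusted p = 0.00259, 10 of 12) and Chil3 (−0.85 ± 0.22, adjusted p = 0.0101, 11 of 12). This list had an adjusted p of 0.00087, and 0.152 with an estimated correlation. In macrophage-named clusters alone Chil3 was 0.48 (adjusted p = 0.55), so its fall rested on the monocyte-named cells.

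Proliferation and resident macrophage lists lay higher. Of 20 proliferation genes 13 rose and 0 fell (18 rose adjusted over the list alone; median 0.85). These included the cyclin gene Ccnb2 (1.51 ± 0.29, adjusted p = 0.000296, 10 of 12), Birc5 (1.499 ± 0.29, adjusted p = 0.000316, 11 of 12), Tyms (1.24 ± 0.27, adjusted p = 0.00159, 11 of 12) and Rrm2 (1.08 ± 0.26, adjusted p = 0.00388, 11 of 12). Camera gave an adjusted p of 3.37e-12, and 0.0373 with an estimated correlation. Of 12 complement and resident macrophage genes 5 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.42). The mannose receptor gene Mrc1 (0.84 ± 0.20, adjusted p = 0.00472) and C1qa (0.42 ± 0.12, adjusted p = 0.0154) rose in 11 of 12, and the transglutaminase gene F13a1 fell (−0.66 ± 0.17, adjusted p = 0.0122, 10 of 12). This list had an adjusted p of 1.29e-05, and 0.0373 with an estimated correlation.

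Of the lists closest to the receptor, the Trem2-dependent list did not pass, while the regulatory macrophage and Trem cluster lists lay lower. Of 25 Trem2-dependent lipid and phagocytosis genes 2 rose, Cd63 and the osteopontin gene Spp1 (1.37 ± 0.23, adjusted p = 7.95e-05, 12 of 12). Another 2 fell, the cholesterol exporter gene Abca1 (−0.58 ± 0.10, adjusted p = 3.97e-05, 12 of 12) and the lipid droplet gene Plin2 (−0.52 ± 0.12, adjusted p = 0.00336, 11 of 12). Adjusted over the list alone 3 rose and 2 fell (median 0.05, adjusted p = 0.655, and 0.80 with an estimated correlation). Of the 17 regulatory macrophage genes, which were recalled from the study itself and are not independent evidence, 1 rose (Spp1) and 7 fell, Trem2 among them (1 and 8 adjusted over the list alone; median −0.48). The interleukin-18 binding protein gene Il18bp (−0.84 ± 0.18, adjusted p = 0.00163, 12 of 12) and Vegfa (−0.88 ± 0.20, adjusted p = 0.00351, 10 of 12) were among the fallen. The list's adjusted p was 1.48e-08, and 0.0497 with an estimated correlation. In the Trem gene cluster Trem3 fell with Trem2 (−1.40 ± 0.29, adjusted p = 0.000755, 12 of 12), while Trem1 (−0.29 ± 0.13, adjusted p = 0.181) did not pass. Of 7 members 2 fell over all genes and adjusted over the list alone (median −0.29; adjusted p = 9.9e-05, and 0.00546 with an estimated correlation). This list and the regulatory macrophage list hold Trem2, the deleted gene, so the knockout itself sets part of their result.

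Of the lymphocyte, stress and stroma lists, none passed with an estimated correlation in monocyte-macrophage-like cells at day 10. Of 6 exhaustion and checkpoint genes the ectonucleotidase gene Entpd1 fell (−0.60 ± 0.11, adjusted p = 6.06e-05, 12 of 12; 1 adjusted over the list alone; median −0.17, adjusted p = 0.0291, and 0.101 with an estimated correlation). Of 4 naive and memory T cell genes 2 fell, among them Il7r (−0.90 ± 0.24, adjusted p = 0.0128, 11 of 12; 2 adjusted over the list alone; median −0.52, adjusted p = 0.00529, and 0.0699 with an estimated correlation). Of 16 dissociation stress genes 2 fell, Ier2 (−0.53 ± 0.14, adjusted p = 0.012, 11 of 12) and Egr1 (−0.89 ± 0.23, adjusted p = 0.013, 11 of 12; 2 adjusted over the list alone). Fos (−0.27 ± 0.11, adjusted p = 0.146) did not pass, nor did the list (median −0.05, adjusted p = 0.0789). None of 11 cytotoxic genes passed over all genes or adjusted over the list alone (median −0.44, adjusted p = 0.00545, and 0.141 with an estimated correlation). Gzmb was at −0.71 ± 0.28 (adjusted p = 0.137). Regulatory T cell genes (3 tested, 0 called, 1 up and 1 down adjusted over the list alone; median −0.07, adjusted p = 0.703) and stroma and tumour cell genes (8 tested, 0 called; median 0.17, adjusted p = 0.703) did not pass as lists.

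At day 19 knockout monocyte-macrophage-like cells carried less of several monocyte transcripts: Chil3, a chitinase-like protein gene of monocytes, the transcription factor gene Cebpb, and Ace and Itgal, which mark patrolling monocytes. Wdfy1, an endosomal adaptor gene, fell most clearly of all genes other than Trem2. Chil3 fell from 320 to 77.6 CPM (−2.01 ± 0.20, adjusted p = 8.12e-10), Cebpb from 410 to 232 CPM (−0.81 ± 0.11, adjusted p = 2.16e-07), each in 12 of 12 knockout plates against the wild type plates of their series. Wdfy1 fell by 2.35 ± 0.18 (adjusted p = 8.14e-18, 12 of 12). Ms4a7 rose again (0.50 ± 0.08, adjusted p = 0.0001, 12 of 12), as did the inhibitory receptor gene Cd72 (280 to 413 CPM, 0.54 ± 0.10, adjusted p = 0.000844, 12 of 12). Of 8671 genes 40 rose and 100 fell, 80 of them by at least 0.5 on the log2 scale. With neighbouring plates, which may not be independent, summed in pairs 31 genes were called (3 risen and 28 fallen, all among these 140). In pairs 20 genes followed for this contrast lost their call, among 49 values that include genes not called as planned. In macrophage-named clusters alone 36 genes were called, 33 of them among these 140. Knockout cells of the class also lay less often in the cluster led by Serpinb10, Adgre4 and Ace (3.33 ± 1.34% and 8.87 ± 3.39%, permutation adjusted p = 0.000245). A fall over the class therefore does not separate fewer monocytes in it from lower levels within cells.

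Other fallen genes at day 19 were the redox enzyme genes Gsr (−1.19 ± 0.16, adjusted p = 3.35e-07) and Msrb1 (−0.65 ± 0.11, adjusted p = 0.0001), and the coagulation factor gene F10 (−1.48 ± 0.23, adjusted p = 4.28e-05), all in 12 of 12. So were Ace (−2.04 ± 0.34, adjusted p = 0.000125), the growth factor receptor gene Met (−1.66 ± 0.30, adjusted p = 0.000448) and the integrin gene Itgal (−0.76 ± 0.14, adjusted p = 0.000692), all in 12 of 12. Gm15564 (−0.96 ± 0.18, adjusted p = 0.000844, 12 of 12) is antisense to another gene, so the source of its reads is uncertain. G530011O06Rik rose by the largest fold (3.23 ± 0.26, adjusted p = 1.56e-16, 12 of 12). Angptl2, a secreted glycoprotein gene (0.89 ± 0.21, adjusted p = 0.0097), the nucleotide metabolism gene Dut (0.68 ± 0.16, adjusted p = 0.0108), the exchange factor gene Fgd2 (0.60 ± 0.16, adjusted p = 0.026) and the kinetochore gene Nuf2 (1.08 ± 0.28, adjusted p = 0.0263) rose in 12 of 12. Ctla2b, a cysteine protease inhibitor gene (0.73 ± 0.15, adjusted p = 0.00204), and the retinoid carrier gene Crabp1 (1.07 ± 0.26, adjusted p = 0.0134) rose in 11 of 12. Crabp1 is also a leading gene of the stroma or tumour-like cluster, and the counts do not separate transcripts carried over from such cells. In the Trem cluster of 7 genes Treml2 rose (0.59 ± 0.14, adjusted p = 0.0138, 12 of 12). Trem3 (−1.22 ± 0.29, adjusted p = 0.0097, 11 of 12) and Trem1 (−0.43 ± 0.12, adjusted p = 0.0328, 10 of 12) fell with Trem2 (1 up and 3 down adjusted over the list alone; median −0.35, adjusted p = 0.000291, and 0.00603 with an estimated correlation, Trem2 included).

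Monocyte and regulatory macrophage genes lay lower at day 19. Of 14 monocyte genes 7 fell and 0 rose (9 fell and 2 rose adjusted over the list alone; median −0.68; adjusted p = 2.28e-13, and 0.00603 with an estimated correlation). These included Chil3, Gsr, F10 and the haptoglobin gene Hp (−1.06 ± 0.25, adjusted p = 0.0115, 12 of 12). Of the 17 regulatory macrophage genes, again not independent evidence, 4 fell and 0 rose (8 fell adjusted over the list alone; median −0.59; adjusted p = 1.75e-16, and 0.00603 with an estimated correlation). Besides Trem2 these were the arginase gene Arg1 (−0.60 ± 0.11, adjusted p = 0.00119), the lectin gene Clec4n (−0.71 ± 0.14, adjusted p = 0.00206) and the metalloproteinase gene Adam8 (−0.45 ± 0.09, adjusted p = 0.00206), each in 12 of 12. Of 20 hypoxia and glycolysis genes the glucose transporter gene Slc2a1 (−0.54 ± 0.14, adjusted p = 0.0359, 11 of 12) and Pfkl (−0.47 ± 0.13, adjusted p = 0.0396, 12 of 12) fell. Adjusted over the list alone 8 fell (median −0.22, adjusted p = 1.39e-08, but 0.123 with an estimated correlation). Vegfa was at −0.66 ± 0.21 (adjusted p = 0.0981). Of 16 NF-kB genes 0 passed, 5 fell adjusted over the list alone (median −0.21, adjusted p = 0.000442, but 0.224 with an estimated correlation). Il1a was at −1.50 ± 0.44 (adjusted p = 0.0612) and Nos2 at −0.86 ± 0.27 (adjusted p = 0.0948).

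Lists that lay higher at day 19 had few members past the threshold. Of 8 stroma and tumour cell genes 3 rose, the matrix protein genes Dcn (0.89 ± 0.22, adjusted p = 0.0165, 12 of 12), Sparc (0.76 ± 0.20, adjusted p = 0.0294, 11 of 12) and Bgn (0.76 ± 0.20, adjusted p = 0.0304, 10 of 12). All 3 are leading genes of the stroma or tumour-like cluster, and the counts do not separate transcripts carried over from such cells. Adjusted over the list alone 4 rose (median 0.71, adjusted p = 3.88e-05, but 0.0945 with an estimated correlation). Of 20 proliferation genes 1 rose, Tuba1b (0.27 ± 0.07, adjusted p = 0.0359, 11 of 12), and 7 adjusted over the list alone (median 0.28, adjusted p = 8.19e-05, but 0.224 with an estimated correlation). Tyms was at 0.57 ± 0.19 (adjusted p = 0.108). Of 11 cytotoxic genes 0 passed and 2 rose adjusted over the list alone (median 0.39, adjusted p = 0.00105, but 0.123 with an estimated correlation). The granzyme genes Gzmc was at 0.88 ± 0.29 (adjusted p = 0.114) and Gzma at 1.07 ± 0.36 (adjusted p = 0.121). Of 12 complement and resident macrophage genes Ms4a7 rose and F13a1 fell (−0.68 ± 0.15, adjusted p = 0.00948, 12 of 12), 5 rose and 2 fell adjusted over the list alone (median 0.22, adjusted p = 0.0574). C1qb was at 0.28 ± 0.09 (adjusted p = 0.0968). MHC class II genes had a median of 0.22 (0 of 9 called over all genes or adjusted over the list alone, adjusted p = 0.0237, but 0.332 with an estimated correlation). H2-Aa was at 0.39 ± 0.20 (adjusted p = 0.363).

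Of the remaining lists at day 19, none passed with an estimated correlation. For 13 MHC class I genes (0 called over all genes or adjusted over the list alone) the median was 0.02, the mean −0.01 and camera's direction down (adjusted p = 0.951), whereas fry's was up, and H2-K1 was at 0.17 ± 0.07 (adjusted p = 0.238). For 26 interferon response genes (0 called either way) the median was −0.01 while camera's direction was up (adjusted p = 0.949). Bst2 was at 0.30 ± 0.09 (adjusted p = 0.0912). Of 25 Trem2-dependent genes Plin2 fell (−0.53 ± 0.11, adjusted p = 0.0025, 12 of 12), and 1 rose and 2 fell adjusted over the list alone (median −0.13, adjusted p = 0.0431, but 0.315 with an estimated correlation). Naive and memory T cell genes had a median of −0.35 (0 of 4 called, 2 down adjusted over the list alone, adjusted p = 0.0183, but 0.123 with an estimated correlation). Exhaustion (median −0.16, adjusted p = 0.0574), regulatory T cell (median 0.15, adjusted p = 0.577) and dissociation stress genes (median −0.09, adjusted p = 0.396) had 0 members called. Entpd1 was at −0.17 ± 0.10 (adjusted p = 0.457), Il2ra at 0.15 ± 0.23 (adjusted p = 0.832) and Zfp36 at 0.23 ± 0.11 (adjusted p = 0.363).

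**Figure D2:**
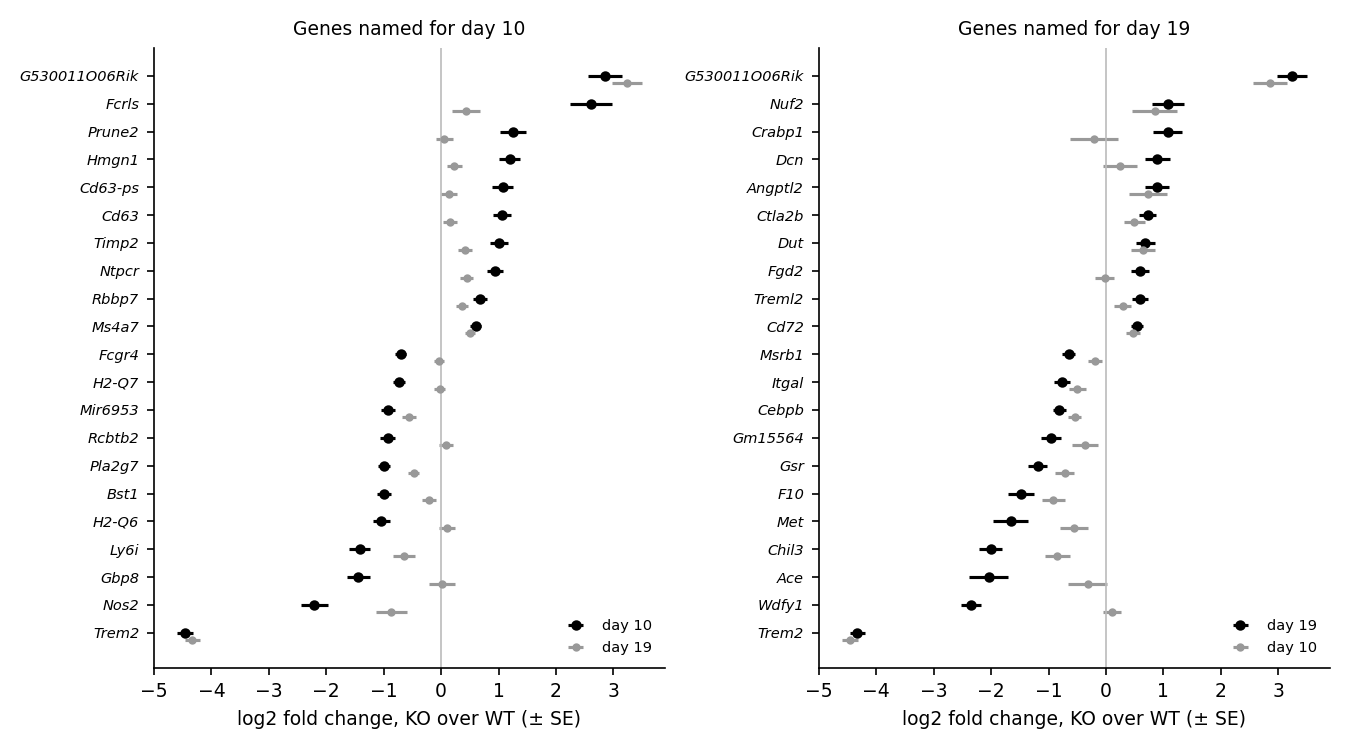
Log2 fold change (knockout over wild type) ± SE of the genes named by rule in monocyte-macrophage-like cells at day 10 (left) and day 19 (right), with black points for the panel's own day and grey for the other day. Pla2g7 fell by 0.99 at day 10, and Wdfy1 and Chil3 fell by 2.35 and 2.01 at day 19.

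The knockout effect itself differed between the days for 71 genes, 41 with a higher and 30 with a lower log2 fold change at day 19 than at day 10. The count was 26 without a series term and 7 with neighbouring plates summed in pairs. In pairs 14 named genes of this contrast lost their call, among 23 values followed that include genes not called as planned. Some MHC class I genes, lower in knockout cells at day 10, were not called at day 19, and Wdfy1 was lower at day 19 alone. The difference between the days was 0.61 ± 0.10 for H2-K1 (adjusted p = 0.000424), 0.42 ± 0.09 for H2-D1 (adjusted p = 0.00744) and 0.49 ± 0.13 for Tap1 (adjusted p = 0.0408). MHC class I and immunoproteasome genes (3 of 13 higher over all genes, 9 adjusted over the list alone; median 0.31) passed with a camera adjusted p of 1.4e-08, and 0.0108 with an estimated correlation. It was −2.45 ± 0.24 for Wdfy1 (adjusted p = 3.52e-12), −1.54 ± 0.30 for Spp1 (adjusted p = 0.00336), −2.18 ± 0.44 for Fcrls (adjusted p = 0.00599), −0.92 ± 0.20 for Cd63 (adjusted p = 0.00744) and −1.20 ± 0.27 for Prune2 (adjusted p = 0.0106). Trem2 showed no such difference (0.13 ± 0.22, adjusted p = 0.92).

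Of 26 interferon response genes 4 were higher in this contrast, and 7 adjusted over the list alone (median 0.19, adjusted p = 3.74e-06, but 0.359 with an estimated correlation). Ifi47 was at 0.85 ± 0.15 (adjusted p = 0.000507), Iigp1 at 1.15 ± 0.24 (adjusted p = 0.00744) and Gbp2 at 0.89 ± 0.23 (adjusted p = 0.0408). Rcbtb2 (1.01 ± 0.18, adjusted p = 0.000702), H2-M3 (1.01 ± 0.19, adjusted p = 0.00125) and H2-Q6 (1.14 ± 0.20, adjusted p = 0.000847), whose reads H2-Q7 could share, were also higher. Of 9 MHC class II genes Ciita was higher (1.41 ± 0.38, adjusted p = 0.049), and 8 higher and 1 lower adjusted over the list alone (median 0.57, adjusted p = 1.88e-06, but 0.113 with an estimated correlation). Cytotoxic genes had 0 of 11 called and 5 higher adjusted over the list alone (median 0.83, adjusted p = 1.88e-06, and 0.0399 with an estimated correlation). The effect on the NK cell-like share rose between the days as well (5.15 points, permutation adjusted p = 0.0119), and the counts do not separate transcripts carried over from NK cells. Gzmc was at 1.47 ± 0.42 (adjusted p = 0.0843) and Gzma at 1.51 ± 0.46 (adjusted p = 0.121). Monocyte genes had Fn1 (−0.86 ± 0.22, adjusted p = 0.0421) and Chil3 (−1.16 ± 0.30, adjusted p = 0.0423) lower (median −0.32, adjusted p = 0.00642, but 0.361 with an estimated correlation). Proliferation genes had 0 called and 5 lower adjusted over the list alone (median −0.65, adjusted p = 0.000606, but 0.361 with an estimated correlation). Birc5 was at −1.04 ± 0.35 (adjusted p = 0.162). Complement (median −0.16, adjusted p = 0.0148, but 0.359 with an estimated correlation), NF-kB (median 0.28, adjusted p = 0.0277, but 0.549) and stroma genes (median 0.33, adjusted p = 0.00881, but 0.361) had 0 called. Mrc1 was at −0.68 ± 0.26 (adjusted p = 0.247) and Nos2 at 1.34 ± 0.36 (adjusted p = 0.0591). Of all called genes, 13 rose and 38 fell on both days and 1, Ly6a, changed in opposite directions, against 1.15 and 3.09 shared by chance if the lists were independent.

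Wdfy1 (chromosome 1, 79702262 to 79776143, mm10) was lower in cells of other classes too. At day 19 in series 82 and 83 it averaged 11.5 ± 4.98 CPM in knockout and 51.9 ± 20.1 in wild type monocyte-macrophage-like cells (SD, n = 12 plates each; permutation p = 1.41e-05), and 15.5 ± 15.97 against 57.5 ± 35.4 in lymphoid cells (permutation p = 0.00149). At day 10 it averaged 65.0 ± 10.5 in 12 knockout and 60.7 ± 9.76 in 7 wild type plates in monocyte-macrophage-like cells (exact permutation p = 0.396), and in lymphoid cells it was higher in knockout plates (81.8 ± 27.3 and 57.7 ± 16.01, exact permutation p = 0.0493). Its log2 fold change was −2.07 in series 82 (adjusted p = 2.6e-07) and −2.68 in series 83 (adjusted p = 3.86e-13). G530011O06Rik (chromosome X, 169975043 to 169978917) averaged 33.6 ± 11.2 against 4.82 ± 2.42 CPM at day 10 and 49.97 ± 9.07 against 4.83 ± 4.83 at day 19 in monocyte-macrophage-like cells.

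**Figure D3:**
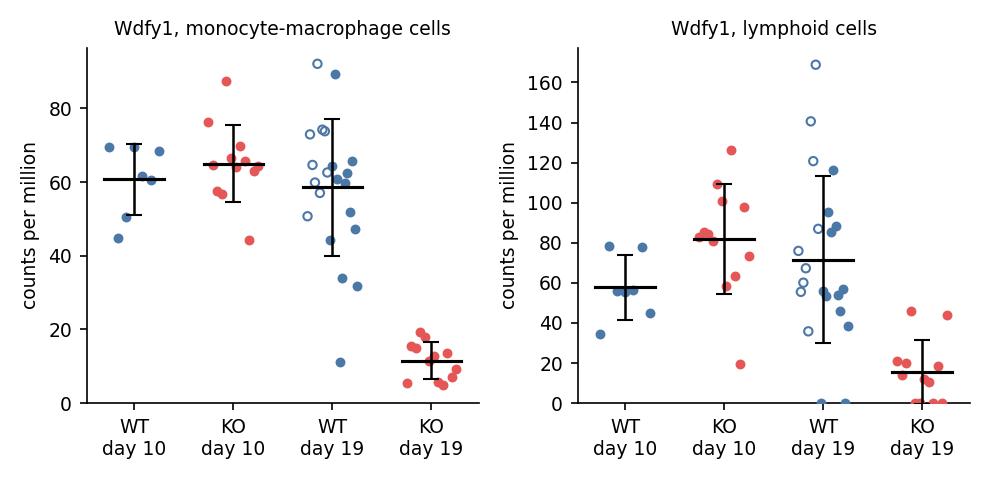
Wdfy1 in CPM per plate, in monocyte-macrophage-like cells (left) and lymphoid cells (right) for the 4 groups, with points for plates, open circles for wild type plates of series 81 and bars for the mean ± SD over all plates of a group. At day 19 the knockout mean was 11.5 CPM in monocyte-macrophage-like and 15.5 in lymphoid cells, against 51.9 and 57.5 in wild type plates of series 82 and 83.

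Between day 10 and day 19 wild type monocyte-macrophage-like cells gained Timp2, Hmgn1 and Prune2, which were also higher in knockout cells at day 10, and lost Pla2g7 and the hypoxia regulator gene Hif1a. Timp2 rose by 1.49 ± 0.15 (adjusted p = 3.88e-12), Hmgn1 by 1.67 ± 0.17 (adjusted p = 6.18e-12), the mitochondrial carrier gene Slc25a4 by 1.41 ± 0.14 (adjusted p = 4.69e-12) and the tetraspanin gene Cd81 by 1.76 ± 0.18 (adjusted p = 7.89e-11) in 21 of 21 plates. Prune2 rose by 1.94 ± 0.20 (adjusted p = 1.05e-11) in 20 of 21. Pla2g7 fell by 1.08 ± 0.09 (adjusted p = 4.13e-15), Hif1a by 1.22 ± 0.11 (adjusted p = 2.07e-13), and Cebpb by 1.01 ± 0.10 (adjusted p = 4.69e-12) in 21 of 21. So did the inhibitory receptor gene Pirb (−1.05 ± 0.09, adjusted p = 2.6e-15) and Ms4a8a (−2.29 ± 0.19, adjusted p = 2.6e-15). In wild type 986 genes rose and 986 fell, and in knockout cells 811 rose and 933 fell. Across 8667 genes, which are not independent replicates, the knockout effect of day 10 and the day effect in wild type had a Pearson r of 0.739, and 77.4% shared a sign. Wild type day 10 cells are in both contrasts, and in simulations with no effect r averaged 0.688 (highest 0.707) and 74.2% shared a sign, little below the observed values. The covariance was 0.106, against 0.0295 on average (highest 0.0310) in the simulations. With separate day 10 plates for the 2 contrasts it averaged 0.0839 over 35 splits (lowest 0.0550), with a mean r of 0.495 (lowest 0.306). Separate plates may still share animals, and the simulations drew plates independently. Day and plate series cannot be told apart.

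In knockout cells the olfactomedin-like gene Olfml3 (1.63 ± 0.16, adjusted p = 1.29e-11), the cyclin gene Ccnb1 (1.96 ± 0.23, adjusted p = 1.3e-09), and Tuba1b (0.62 ± 0.07, adjusted p = 1.91e-09) rose from day 10 to day 19 in 12 of 12 plates. So did Angptl2 (1.76 ± 0.22, adjusted p = 3.37e-09) and Crabp1 (2.50 ± 0.30, adjusted p = 2.4e-09). Crabp1 is a leading gene of the stroma or tumour-like cluster, and transcripts carried over from such cells are not separated. Wdfy1 (−2.50 ± 0.17, adjusted p = 1.96e-19), Cebpb (−1.32 ± 0.10, adjusted p = 2.38e-16), Pirb (−0.91 ± 0.09, adjusted p = 1.66e-12), Ms4a8a (−2.17 ± 0.21, adjusted p = 2.5e-12) and Ms4a6d (−0.77 ± 0.08, adjusted p = 3.23e-12) fell in 12 of 12. Trem2 did not pass between the days in wild type (0.25 ± 0.10, adjusted p = 0.0781, 16 of 21) or in the residual counts of knockout cells (0.23 ± 0.20, adjusted p = 0.513). The knockout plates of the 2 days also differed in sex-linked transcripts. Y-linked counts exceeded Xist in all 12 at day 10 and in 4 of 12 at day 19. Day, plate series and sex are therefore mixed in the knockout day contrast.

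In T cell-like cells few genes differed between the genotypes. At day 10 (10 knockout and 7 wild type plates) Bst2, an interferon-inducible antiviral gene, rose from 268 to 529 CPM (0.99 ± 0.23, adjusted p = 0.0361, 10 of 10). Klra5, a gene of the Ly49 receptor family, fell (−4.04 ± 0.70, adjusted p = 0.000728, 10 of 10). Xist also fell and is named after its values were seen, and it follows the sex difference given above. These 3 were the calls among 2052 genes. Without wild type replicate 6, whose Klra5 level was the highest, Klra5 was at −3.37 (adjusted p = 0.00828) and Bst2 at 0.94 (adjusted p = 0.0855), and near-identical Klra genes leave the source of its reads uncertain. Of 23 interferon response genes Bst2 rose and 4 rose adjusted over the list alone (median 0.37, adjusted p = 5.34e-05, but 0.173 with an estimated correlation). Isg15 was at 1.02 ± 0.27 (adjusted p = 0.134). Monocyte genes (median 0.32, adjusted p = 0.0302, but 0.173 with an estimated correlation) and proliferation genes (median −0.11, adjusted p = 0.00876, but 0.538 with an estimated correlation) had 0 members called. Ly6c2 was at 0.56 ± 0.17 and Cenpa at −0.98 ± 0.30 (adjusted p = 0.291 each).

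At day 19 (8 knockout plates, and 7 wild type plates of series 82 and 83) the edgeR quasi-likelihood test called 0 of 2052 genes in T cell-like cells, with 153 at an unadjusted p under 0.05. Some lists of myeloid, stroma and stress transcripts lay higher with the preset correlation, and none passed with an estimated one. They were MHC class II (median 1.55, adjusted p = 0.0019, but 0.221 with an estimated correlation) and stroma and tumour cell (median 0.83, adjusted p = 0.00315, but 0.128). Dissociation stress (median 0.59, adjusted p = 0.00315, but 0.0701), complement (median 0.62, adjusted p = 0.0435, but 0.381) and Trem2-dependent genes (median 0.18, adjusted p = 0.044, but 0.381) lay higher likewise. Fry called the dissociation stress (adjusted p = 0.0238) and stroma lists (adjusted p = 0.0377). Bgn was at 1.96 ± 0.56 (adjusted p = 0.309), Ms4a7 at 1.69 ± 0.60 (adjusted p = 0.519), H2-Eb1 at 2.35 ± 1.15 (adjusted p = 0.649), Zfp36 at 1.42 ± 0.54 (adjusted p = 0.519) and Ctsz at 1.08 ± 0.38 (adjusted p = 0.519).

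NK cell-like cells at day 10 (4 knockout and 5 wild type plates) had 0 of 3378 genes called by edgeR, 127 at an unadjusted p under 0.05, and 0 by DESeq2. Interferon response genes lay higher (21 tested, 0 called; median 0.37, adjusted p = 0.0149, but 0.517 with an estimated correlation). Bst2 was at 0.88 ± 0.32 and Irf7 at 0.80 ± 0.34 (adjusted p = 0.999 each). Ndrg1 was at −1.73 ± 0.45 (adjusted p = 0.999). On data simulated at this size 72.6% of genes changed 4-fold were called and 19.7% of those changed 2-fold. At day 19 a fit with at least 5 NK cells per plate called 0 of 1167 genes (83 at an unadjusted p under 0.05).

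Over all kept cells, without rebuilt classes, 135 genes rose and 112 fell of 10183 at day 10, and 19 rose and 72 fell at day 19. Of 12 complement and resident macrophage genes 7 rose at day 10 (10 adjusted over the list alone; median 0.70, adjusted p = 4.49e-14, and 0.000981 with an estimated correlation). Of 14 exhaustion and checkpoint genes 3 fell at day 10 (8 adjusted over the list alone; median −0.46, adjusted p = 1.68e-05, and 0.0204 with an estimated correlation). The T cell-like share was lower too (8.71% and 12.4%), and within T cell-like cells 0 of 11 members passed (median −0.15, adjusted p = 0.0833, and 0.336 with an estimated correlation). Of 20 proliferation genes 0 rose and 2 fell at day 10 (5 fell adjusted over the list alone; median −0.26, adjusted p = 3.29e-05, but 0.134 with an estimated correlation), the opposite of the monocyte-macrophage class. At day 19 monocyte genes lay lower (6 fell, 10 adjusted over the list alone; median −0.50, adjusted p = 1.5e-10, and 0.012 with an estimated correlation).

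T cell-like cells were a smaller share of the CD45-positive cells in knockout tumours on both days, and NK cell-like cells a larger share at day 19. At day 10 T cell-like cells made up 8.71 ± 1.72% of kept cells in knockout (SD, n = 12) and 12.4 ± 1.34% in wild type plates (n = 7). The difference was −3.68 points (exact permutation p = 0.000159, adjusted p = 0.00143, 12 of 12 plates). At day 19 they made up 6.93 ± 1.44% and 9.31 ± 2.08% (n = 12 each; −2.38 points, permutation p = 0.00394, adjusted p = 0.0177, 11 of 12). The difference was −2.85 points in series 82 (exact p = 0.0195) and −1.91 in series 83 (exact p = 0.0952). Under the alternatives its adjusted p ranged from 0.00306 to 0.115 and did not pass with neighbouring plates summed in pairs (0.09), at least 200 UMIs (0.0583), resolution 0.5 (0.0614) or a mitochondrial limit of 15% (0.115). NK cell-like cells made up 6.36 ± 1.85% of knockout and 3.24 ± 1.27% of wild type cells at day 19 (3.12 points, permutation p = 9.37e-06, adjusted p = 8.43e-05, 12 of 12). The difference was 3.88 points in series 82 and 2.36 in series 83 (exact p = 0.00433 each). At day 10 the NK shares were 7.14 ± 2.39% and 9.18 ± 3.45% (adjusted p = 0.365), and the change of the effect between days was 5.15 points (permutation p = 0.00132, adjusted p = 0.0119).

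Monocyte-macrophage-like cells made up most cells of every group, and their share did not pass as planned. It was 71.5 ± 7.71% and 67.2 ± 5.14% in knockout and wild type at day 10 (adjusted p = 0.365) and 79.7 ± 2.41% and 78.5 ± 3.57% at day 19 (adjusted p = 0.448). The difference at day 19 passed at −7.56 points with at least 200 UMIs (adjusted p = 0.0144) and at 5.20 points with all plates pooled (adjusted p = 0.0318). Neutrophil-like cells made up 0.381 ± 0.470% of knockout and 2.22 ± 2.58% of wild type cells at day 19 (−1.84 points, permutation p = 0.00779, adjusted p = 0.0234, 12 of 12), though not within series 82 alone (exact p = 0.184, and 0.0238 in series 83). Of the 50 wild type cells, 10 and 14 came from replicates 20 and 21, which kept under 60% of their wells. Without such plates the difference was −0.443 points (adjusted p = 0.211, in a range of 0.00994 to 0.288 over the alternatives). Neutrophil-like cells held a median of 650 UMIs, 0.287 of that of their plates, so the minimum of 400 UMIs sets how many were counted. The 9 wild type plates of series 81 held 16.4 ± 3.38% T cell-like, 5.69 ± 2.87% NK cell-like and 69.2 ± 3.81% monocyte-macrophage-like cells, so wild type shares at day 19 also differed between series.

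**Figure D4:**
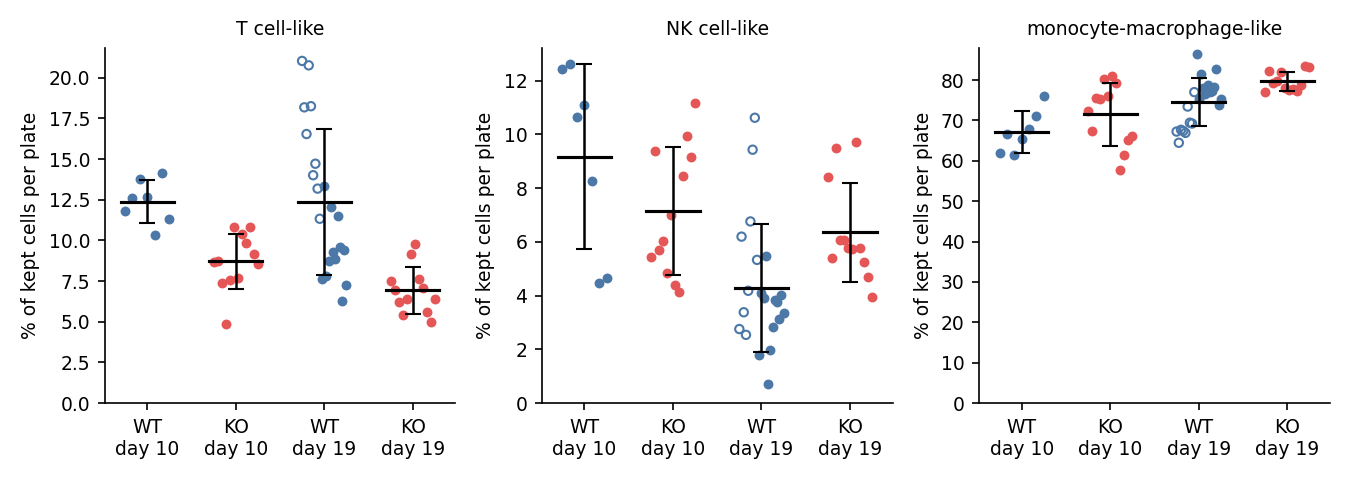
Percent of kept cells per plate that were T cell-like, NK cell-like and monocyte-macrophage-like, for the 4 groups, with points for plates, open circles for series 81 and bars for the mean ± SD over all plates of a group. T cell-like cells averaged 8.71% in knockout and 12.4% in wild type plates at day 10, and NK cell-like cells 6.36% and 3.24% at day 19 in series 82 and 83.

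From day 10 to day 19 knockout plates gained monocyte-macrophage-like cells (8.19 points, permutation adjusted p = 0.00355) and stroma or tumour-like cells (1.51 points, adjusted p = 0.00355). They lost dendritic (−3.26 points, adjusted p = 0.00355), T (−1.78 points, adjusted p = 0.0190), neutrophil (−2.01 points, adjusted p = 0.00663) and B cell-like cells (−0.626 points, adjusted p = 0.00408). Wild type plates gained monocyte-macrophage-like cells (7.32 points, adjusted p = 0.0328) and lost NK cell-like cells (−4.89 points, adjusted p = 0.00578). The wild type mean of day 19 mixes series: monocyte-macrophage-like cells were at 69.2% in series 81 and 78.5% in series 82 and 83, against 67.2% at day 10, and NK cell-like cells at 5.69% and 3.24%, against 9.18%. Changes between days cannot be told from changes between series in either genotype. In the knockout they also cannot be told from sex, given the Y-linked counts above.

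NK cell-like cells of knockout tumours at day 19 lay more often in the cluster led by Gzma, Klra8 and Ncr1 (191 of 235 cells, 81.3%) than those of wild type (63 of 99, 63.6%; 17.8 points, permutation p = 0.00243, adjusted p = 0.0121). The remaining cells lay in a cluster led by the granzyme genes Gzmd, Gzmg and Gzme (44 of 235, 18.7%, and 36 of 99, 36.4%). The perforin gene Prf1 was also among the leading genes of this second cluster, so both clusters carried cytotoxic genes. At day 10 the first of these clusters held 82.5% and 74.9% (exact permutation p = 0.178). Shares of the Cd8, Foxp3 and Cd4 clusters within T cell-like cells did not pass on either day.

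The monocyte-macrophage class was clustered without the genes called, so that these could not make the clusters directly. Genes that vary with them stayed in, and the leading genes given are those not called. In the cycling cluster 7 of the 10 leading genes of all were called. Knockout tumours at day 19 held fewer cells of the cluster led by Serpinb10, Treml4 and Spn, genes of patrolling monocytes (4.17 ± 1.28% and 10.1 ± 4.55% in wild type; permutation p = 8.9e-05, adjusted p = 0.00107, 12 of 12 plates). They also held fewer cells of the cluster led by the heat shock genes Hspa1a and Hspa1b and the matrix protease gene Mmp12 (3.28 ± 1.59% and 6.32 ± 2.31%; permutation p = 0.00112, adjusted p = 0.00675, 12 of 12). More cells were led by Ch25h, Ccl7 and Olfml3 (20.98 ± 4.78% and 15.6 ± 5.82%; permutation p = 0.0103, adjusted p = 0.0413, 10 of 12). At day 10 this Ch25h cluster did not pass (16.9 ± 4.62% and 12.4 ± 3.31%, exact permutation adjusted p = 0.0811, 9 of 12). Knockout tumours of day 10 held fewer cells led by Slpi, Ptgs2 and Il1b (6.74 ± 2.11% and 10.1 ± 2.48%, exact permutation adjusted p = 0.014, 12 of 12). Fewer were led by MHC class II genes (19.3 ± 4.28% and 25.9 ± 3.59%, adjusted p = 0.014, 11 of 12) and by Malat1 (2.98 ± 1.22% and 6.30 ± 1.49%, adjusted p = 0.00167, 12 of 12). Larger at day 10 were the cycling cluster led by Cenpf and Top2a (2.82 ± 1.81% and 0.393 ± 0.645%, adjusted p = 0.014, 10 of 12) and a cluster of low depth led by mitochondrial and ribosomal genes (14.8 ± 6.83% and 7.59 ± 3.37%, adjusted p = 0.0443, 9 of 12). Of 12 clusters 5 passed at day 10 and 3 at day 19.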

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

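The gene-wise test of the difference between days and the splits of the plates were planned. The other tests of explanations, and that of the difference between days in the NK share, were chosen after the results were seen.

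In T cell-like cells of wild type replicate 6 at day 10 Klra5, a gene of the Ly49 receptor family, stood at 299.7 CPM, against 11.7 to 82.1 in the other 6 plates, which made it a plate far from the rest (gap over range 0.755). It was the only one among 75 groups of 4 to 10 plates examined in this way, and chance alone gives about 1 in 20 groups. No explanation was tested.

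The knockout effect differed between the days by a test of the difference itself for 71 genes in monocyte-macrophage-like cells. Those named were H2-K1 (0.61), Ifi47 (0.85), Rcbtb2 (1.01), H2-Q6 (1.14) and H2-M3 (1.01), with a higher log2 fold change at day 19, and Wdfy1 (−2.45), Spp1 (−1.54), Fcrls (−2.18), Cd63 (−0.92) and Prune2 (−1.20), with a lower one. The same test picked 9 lists, with medians of 0.19 for interferon response, 0.57 for MHC class II, 0.31 for MHC class I, 0.28 for NF-kB, 0.83 for cytotoxic and 0.33 for stroma and tumour cell genes. Medians were −0.16 for complement, −0.32 for monocyte and −0.65 for proliferation genes. Of these lists, MHC class I and cytotoxic genes passed with an estimated correlation. Other splits of the plates reached at most 44 genes, and only the real one of 100 gave 71 or more (1 of 100), so chance can be excluded for the count if plates are independent. Neighbouring plates were correlated, and with them summed in pairs the count was 7. The day 10 side of each difference carries the sex difference of those plates.

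Wdfy1 was lower in knockout tumours at day 19 and not at day 10. If loss of Trem2 acted within the cells that express it, lymphoid cells would not share the difference, but in them Wdfy1 was 41.9 CPM lower (−41.9, permutation p = 0.00149), whereas at day 10 it was higher in them (exact permutation p = 0.0493). Macrophage RNA counted in other wells is argued against by the wild type lymphoid cells, where Wdfy1 stood at 111% of its macrophage level and Trem2 at 6.37%. Sequencing batch is argued against by the difference within both series 82 and 83 (larger adjusted p = 2.6e-07). What stays open, and was not tested, is another genetic or environmental difference between the animals, since a locus on chromosome 1 that differs between them could lower Wdfy1 in every cell type.

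The NK cell-like share was higher in knockout plates at day 19, and the effect differed between days by 5.15 points. Shallow wild type plates are argued against by the difference of 2.42 points that remained without plates under 60% of wells kept (adjusted p = 0.0276). Sex of the animals is argued against by the 2.64 points that remained without the 4 knockout plates with Y-linked transcripts (adjusted p = 0.00122). The spread of wild type tumours between plate series stays open: wild type plates of series 81 averaged 5.69% NK cell-like cells, nearer to the knockout mean of 6.36% than to the wild type mean of 3.24% in series 82 and 83. An effect of Trem2 loss on NK cells may therefore be mixed with differences between groups of mice that the labels do not name.

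Wells listed without a cell held a median of 37.5 UMIs, a signal outside the measured cells, and 0 of 208 reached 400 UMIs. In wild type replicate 19 of day 19, 7 Y-linked counts lay in 7 of 318 cells, none of which held Xist, and 6 of the 7 were monocyte-macrophage-like. These counts were too few for a test, and no explanation was tested.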

How the results depend on the processing

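Alternatives added after the data were seen are those on shallow plates, paired sums, Y-linked transcripts, mitochondrial rRNA, series 81, blocks within series 82, single plates, a minimum of 5 cells, and clustering without called genes; the others were planned. Of 110 gene counts 71 stayed within 1.5 times the planned value, as did both day contrasts under every alternative run. Of 2090 values of named genes 1764 kept direction and side of the threshold, 286 kept direction only, 33 passed anew and 7 changed sign. Of 208 class shares 175, and of 112 list tests 70, kept both. Where a value below differs, the cause was not tested unless stated.

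For genes in monocyte-macrophage-like cells, day 10 calls numbered 438 to 639 under 10 alternatives. They fell from 518 to 134 with a term for Y-linked transcripts, 246 with neighbouring plates summed in pairs and 84 with cells thinned to 400 UMIs. With the Y-linked term the 514 called genes other than Trem2 and sex-linked genes kept a median size of 0.631 (0.618 without it), and 99.4% kept their sign. Only among the knockout plates of day 19 do plates of 1 group differ in these transcripts, so those plates alone set the term. Neither the lost calls nor the kept median can therefore show what sex did at day 10. The day 19 count of 140 became 213 with the DESeq2 Wald test, 386 without a series term, 9 and 21 in series 82 and 83 alone (fewer plates), 62 without shallow plates, 31 in pairs, 36 in macrophage-named clusters, 87 with marker sums and 60 thinned. The count of 71 between days became 162 with the Wald test, 26 without a series term, 35 with the Y-linked term and 7 in pairs. Over all cells the day 10 count of 247 became 21 with the Y-linked term and 136 in pairs. The day 19 count of 91 became 164 with the Wald test, 385 without a series term, 8 and 14 in series 82 and 83 alone, 21 without shallow plates, 28 without the plates with Y-linked transcripts, 44 with the Y-linked term and 17 in pairs. The rise without a series term has a cause in the construction, since 9 wild type plates of series 81 then enter.

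In T cell-like cells the 3 calls of day 10 became 11 without a filter on low counts, 1 with 800 UMIs, 1 with the Y-linked term and 5 in pairs, with 2 left without wild type replicate 6. The 0 calls of day 19 became 6 without a filter, 2 without a series term, 3 without the plates with Y-linked transcripts, 3 with the Y-linked term and 1 in pairs. By edgeR 153 genes had an unadjusted p under 0.05 at day 19, and the Wald test called 0 (175 unadjusted). In NK cell-like cells the 0 calls of day 10 (edgeR, 127 unadjusted; Wald test 0, 64 unadjusted) became 1 without a filter and 2 in pairs. Without each of its 9 plates in turn they stayed at 0, with 103 to 167 genes unadjusted.

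Single genes that changed sign were Chil3 at day 10 (0.48 in macrophage-named clusters) and 6 values of uncalled genes. These were Trem1 at day 10 (0.53 in thinned cells), Il2ra at day 19 (−0.029 without a series term, −0.095 in series 83 and −0.069 without shallow plates), Ctsz in T cell-like cells (−0.54 with 800 UMIs, where 1 knockout plate was left against 12 wild type plates and was taken to vary as they do) and Irf7 in NK cell-like cells (−0.50 with the Y-linked term).

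Class shares depended on the filters. With 200 UMIs the differences in points at day 10 were −3.22 for dendritic, 0.516 for neutrophil and 0.760 for stroma cells, and at day 19 −1.78 for T (not past the threshold), 3.39 for dendritic (not past), −7.56 for monocyte-macrophage and 5.66 for stroma cells (both past the threshold, with the sign changed). With a mitochondrial share of at most 15%, which left 5799 cells, they were 0.360 for NK, −3.31 for T (not past), −0.811 for monocyte-macrophage and 1.03 for neutrophil cells at day 10, and −2.27 for T (not past), 0.741 for dendritic and 0.604 for stroma cells at day 19. With 800 UMIs they were −0.0388 for B cells at day 10, and 0.0848 for dendritic and −0.310 for neutrophil cells (not past) at day 19. Marker sums gave −1.71 for B cells, −1.26 for mast and 2.95 for stroma cells at day 19, all past the threshold and the last 2 with the sign changed. Resolution 0.5 gave −2.01 for T cells at day 19 (not past), and resolution 2.0 gave 0.0203 for neutrophils at day 10 and 0.267 for dendritic cells at day 19. At day 19 dendritic cells were at 0.182 without the plates with Y-linked transcripts, 0.104 without mitochondrial rRNA and 0.0868 without called genes. Neutrophils no longer passed at −1.65 without the plates with Y-linked transcripts, −0.443 without shallow plates, −1.84 in pairs (T cells −2.42) and −0.889 with all plates of the day pooled, where monocyte-macrophage cells passed at 5.20 and stroma cells were at 0.195. Clusters past the threshold at day 19 numbered 3 without called genes, against 5. The T cell decline at day 10 kept its direction under each alternative run and its side of the threshold except with the limit of 15%, and the NK cell rise at day 19 kept both under each.

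With an estimated correlation in camera, adjusted p at day 10 was 0.122 for interferon and MHC class II, 0.152 for monocyte, 0.102 for hypoxia, 0.0699 for NF-kB and naive T cell, 0.141 for cytotoxic and 0.101 for exhaustion genes. At day 19 it was 0.315 for Trem2-dependent, 0.332 for MHC class II, 0.123 for hypoxia, cytotoxic and naive T cell, 0.224 for NF-kB and proliferation, and 0.0945 for stroma genes. For the difference between days it was 0.359 for interferon and complement, 0.113 for MHC class II, 0.361 for monocyte, proliferation and stroma, and 0.549 for NF-kB genes. Lists called fell to 0 in T (both days) and NK cells, and to 3 and 2 over all cells at day 10 and 19. With fry, day 19 values were 0.218 for Trem2-dependent, 0.0958 for MHC class II and NF-kB, and 0.776 for MHC class I genes, in the opposite direction. Between days they were 0.0587 for interferon, 0.228 for complement, 0.277 for monocyte, NF-kB and proliferation, and 0.135 for stroma genes. Fry called 0 lists in T cells at day 10, 2 at day 19, 0 in NK cells and 5 over all cells at day 19.

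No paired analysis was possible because replicate numbers follow only the order of deposition and the labels do not say which plates of different groups share an animal, a tumour or a preparation; this concerns pairs named by the labels. Plate numbers alternate between the genotypes in series 82, not at day 10 or in series 83, so series 82 alone was also fitted in 3 blocks of 4 plates by number. In monocyte-macrophage-like cells this called 16 genes (12 of them among the 140), against 9 without blocks, and 24 of 49 named values kept their side of the threshold, against 22. Over all cells it called 26 (17 among the 91), against 8, and in T cell-like cells 0. The fits by animal in place of plate were not run, since the labels name no animals, and the planned NK fit at day 19 could not be estimated. Its alternatives called 19 genes without a series term, where the wild type plates are of series 81, 1 in pairs, and 0 of 1167 with at least 5 cells a plate (83 at an unadjusted p under 0.05, edgeR). T cell-like cells numbered 266 and 246 in the wild type and knockout plates fitted at day 10, and NK cell-like cells 172 and 99. On simulated data of these sizes 63.3% of 2-fold changes were called in T and 19.7% in NK cell-like cells, so depth limits what the NK test could detect, while the 0 calls are not put down to it alone.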

Other observations

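The comparisons of cell class shares and the splits of the plates were planned, whereas the tests of sex, of neighbouring plates and of explanations in this part were chosen after the results were seen.

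The sorted cells included 350 stroma or tumour-like cells led by Col3a1, Dcn and Sparc, matrix genes, although the sort was for CD45. Their median depth was 10361.5 UMIs, and they made up 2.95 ± 0.929% of knockout and 3.18 ± 1.08% of wild type cells at day 19 (SD, n = 12 plates each; permutation p = 0.581). Dendritic cell-like cells made up 5.52 ± 2.66% and 3.97 ± 1.99% at day 10 (exact permutation adjusted p = 0.365) and 2.25 ± 1.03% and 2.32 ± 0.760% at day 19 (permutation adjusted p = 0.869). B cell-like cells were rare, with 22 knockout and 13 wild type cells at day 10 and 5 and 9 at day 19.

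Between the 4 knockout plates of day 19 with Y-linked transcripts and the 8 with Xist, 4 genes differed in monocyte-macrophage-like cells by edgeR. Besides the sex-linked Eif2s3y, Ddx3y and Xist this was Cd93, a receptor gene of phagocytes, which was higher in the plates with Y-linked transcripts (0.48 ± 0.10, adjusted p = 0.0486). Across genes the knockout effects of day 10 and day 19 correlated with Pearson r = 0.230, and genes are not independent replicates. Neighbouring plates of a group and series were more alike than others, with a mean correlation of 0.252 over 25 pairs against −0.199. Both values are of deviations from group means, which lowers them. The likeness was strongest in the knockout plates of day 10 (mean 0.611 over 6 pairs, lowest 0.444), against means of 0.0591 to 0.218 in the other groups and series. Plates may thus be less independent than the tests assume, and with pairs summed the day 10 count was 246.

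The day 10 differences in monocyte-macrophage-like cells were weighed first against the sex of the animals, which the design cannot separate from genotype at that day. If sex acted alike on both days, the called genes would differ between knockout plates of day 19 with and without Y-linked transcripts by at least 0.5 of their day 10 size of 0.618, but their median there was −0.034, within the other assignments of these plates (−0.060 to 0.068). A sex effect present at day 10 alone stays open. So does one on a smaller part of these genes on both days, which a median does not show. The 4 plates with Y-linked transcripts were neighbours, 2 per series. They were assigned singly, although neighbouring plates may not be independent. Another mix of monocyte-named and macrophage-named cells is argued against as the whole cause by 398 of the 518 genes called with the same sign in macrophage-named clusters. Those clusters are themselves mixed, led by Ch25h and Fcrls, by MHC class II or by cell cycle genes. Cluster shares within the class also differed at day 10, so another mix among macrophage-like cells stays open. A state like that of wild type cells at day 19 may add to the differences, as a hypothesis that leaves sex and tumour stage open: with separate wild type controls of day 10, the covariance across genes of the knockout and day effects stayed above 0 in all 35 splits (lowest 0.0550). These control plates are of 1 series and may share animals. A deviation common to them would enter both effects, and the splits cannot exclude it.

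Other splits of the same plates into groups of the same sizes were tested for each gene count, 100 each with the real one. They treat plates as independent, although neighbouring plates were correlated. In monocyte-macrophage-like cells the real split alone (1 of 100) reached 518 genes at day 10 (highest other 27) and 140 at day 19 (highest other 1). The same held for 1972 genes between days in wild type (highest other 584) and 1744 in knockout cells (highest other 85). Over all cells it held for 247 genes at day 10 (highest other 27) and 91 at day 19 (highest other 1), so chance can be excluded for these counts if plates are independent. With neighbours summed in pairs the counts were 246 and 31 in the class and 136 and 17 over all cells. For the number of lists called, the real split alone reached 11 lists at day 19 (1 of 100, highest other 9). These include the Trem cluster and regulatory macrophage lists, which hold Trem2, the deleted gene. Lists were not counted without them in the splits, so chance is not excluded for the other lists of day 19. At day 10 it cannot be excluded either (13 lists, 6 of 100, highest other 15). In T cell-like cells 3 of 100 splits gave 3 genes or more at day 10 (highest other 10). Chance can be excluded for that count only if plates are independent. A split with 10 calls shows that another grouping of these plates can give more calls, for a cause that was not tested. Of the 3 genes Xist follows sex and Bst2 did not pass without wild type replicate 6 (adjusted p = 0.0855). All 100 matched the 0 genes of day 19 (highest other 1; edgeR, 153 at an unadjusted p under 0.05; DESeq2 Wald test 0). In NK cell-like cells all 100 matched 0 genes at day 10 (127 at an unadjusted p under 0.05; Wald test 0), and another split gave 92 calls, for a cause that was not tested either.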
